A study of Mus musculus with 30 samples.

How the data were processed

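Liver RNA of CD-1 mice was sequenced in 30 libraries as single-end 125 bp reads on 1 instrument type (HiSeq2500), with an RNA integrity number of at least 7 for each sample per the labels. According to the submitters' notes the reads were checked with FastQC, aligned with STAR to the mouse genome build mm10 and counted per gene with featureCounts, with versions not given in the sources used here. PND1 and PND21 libraries were read on 1 lane and PND42 libraries on another.

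The deposited tables hold log2 values per gene and library, which the authors made by dividing read counts by a library size factor, adding 1 and taking the log2. This was read from the values: the whole reads behind each library came back with 100% of values within 0.1 of a whole number. The deposited signal column (baseMean) equals the mean of the normalised counts over 14 libraries in the PND1 and PND21 tables and over 16 libraries for PND42, so that the authors scaled PND1 and PND21 together and PND42 apart. The PND1 and PND21 tables also hold the authors' own log2 fold changes and p_value columns, which were used only for the counts attributed to the authors. The deposited p values (p_value) came with the authors' test of exposed against control at each of these ages, and the adjusted p values were made from them by the authors before deposit, by a tool not given in the sources used here. The tables list 14259 genes at PND1 and PND21 and 13091 at PND42, with a lowest mean of 10.5 and 12.1 normalised counts, and 12795 genes are in all of them. Genes below those means are not analysed here. The smallest read total was 22.0 M reads and the largest 40.1 M reads, and a difference in genes near the lowest mean is limited by counting error.

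Gene symbols are those of the tables, and positions, intron lengths and gene types are from GENCODE vM21 on the same build. Of the 14259 identifiers at PND1 and PND21, 14238 were in that annotation. Libraries were grouped by the age, sex and exposure in the labels. Among PND42 controls, 1 female and 3 male columns could be tied to their group but not to a replicate number, and are called unnumbered. The name of the unnumbered female column carries the tag that the labels give to PND21 Control replicate 1, so that its sample is uncertain. It was not a copy of that library, with 0.07% of genes at the same read count among those with at least 100 reads in either, and its correlation with it was 0.903 against 0.888 to 0.91 for the other 3 PND42 female controls. Sample tags begin with 18 different numbers, of which 9 occur in at least 2 groups, and within each group the leading numbers all differ. Whether they mark litters is not given in the sources used here, and shared litters across groups were not modelled. Replicate numbers did not pair exposed with control animals in the values, so no paired result is given beside the comparisons. No paired analysis was possible in males because control and exposed males share fewer than 2 numbers.

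The comparisons, the gene lists and the alternatives were fixed before the data were examined, on the assumption that the tables would hold read counts. Because the values are on a log2 scale, the planned count models were not used, and limma (version 3.58.1, R 4.3.3, with the data.table package at 1.17.8) was fitted to the deposited log2 values in their place, with an intensity trend and robust empirical Bayes. Genes with at least 10 normalised counts in at least as many libraries as the smallest group were tested, all tests were two-sided, and p values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The PND42 comparisons shared 1 fit of 4 groups. The interaction across ages was a joint F test of the 3 female exposure effects. A comparison of PND42 with PND21 controls was planned and is not reported, since these tables were scaled separately. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, then with a correlation estimated from the data, and with fry, which asks whether a list moves on balance 1 way. Beside counts over all genes, members were also adjusted over the list alone. Directions are relative to the median gene under the deposited scaling.

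Named genes followed a fixed rule: Mt1 and Mt2 in each exposure comparison, the 12 highest and 12 lowest fold changes among passing genes with every exposed library on 1 side of the control mean (8 and 8 for sex and age), the 10 genes of lowest p where fewer than 10 passed, up to 4 members of lowest p from each list, the 8 genes of lowest adjusted p for the interactions, and Afp, H19, Igf2, Hbb-bs, Alas2, Xist, Ddx3y and Alb as reference levels. For 1 gene that met the rule the result is not reported here. Gm11273, 2310007B03Rik and Gm8730 are named under the part of the rule for the genes of lowest p. Single measures per library were compared with two-sided exact permutation tests. The share of mitochondrial reads, the level of genes with over 300 kb of intron and of Malat1 and Neat1 were chosen as measures after the PND42 results were seen.

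Results were also computed with limma voom with sample quality weights on the recovered whole reads, no filter, a mean of at least 1 read per M reads, a replicate block, a fit of the compared groups alone, the erythroid mean as a covariate, and leaving out each library, all as fixed beforehand. Scaling by a trimmed mean of M values or by total reads, pseudocounts of 0.5 and 5, and removal of each library's trend with intron length or GC content were added after the data were seen. The fits were tested on simulated data, in which 200 genes were changed in libraries of the same size and spread. The changed genes were drawn from genes with means above the lowest ones tested, and genes varied independently of each other. Recovery in the real data may therefore be lower. At a 4-fold change, 93% were recovered at PND1, 71% at PND21, 92% in PND42 females and 91% in PND42 males. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.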

Results

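The study asked how exposure to cadmium before birth altered the liver transcriptome at 3 ages after birth. Liver RNA was sequenced from CD-1 mice, an outbred stock, that had been exposed during gestation to cadmium chloride at 500 ppb or had served as controls. At postnatal day (PND) 1 there were 4 control and 4 exposed females, at PND21 there were 3 and 3 females, and at PND42 there were 4 control and 4 exposed mice of each sex, which made 30 libraries. The labels do not say which animals were litter mates, and each was treated as independent. Read totals over the genes in the tables, in M reads, were 24.4 to 27.8 in PND1 controls and 25.4 to 29.6 in PND1 exposed females. They were 22.0 to 24.6 in PND21 controls and 24.8 to 28.3 in PND21 exposed females. At PND42 they were 28.7 to 40.1 in control and 30.2 to 35.4 in exposed females, and 27.7 to 32.3 in control and 27.8 to 37.4 in exposed males. Every PND21 exposed library was therefore deeper than every PND21 control library, while the ranges overlapped in the other comparisons. Gene levels are given below as normalised read counts (mean ± SD) and differences as log2 fold changes of exposed over control (± SE). A gene was counted as changed at an adjusted p under 0.05 over all genes tested.

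In newborn females the comparison asked which liver genes differed at birth after exposure in the womb. Nuclear genes of mitochondrial energy production had lower mean levels in the exposed livers. Of 73 measured nuclear-encoded genes of oxidative phosphorylation, the respiratory chain that makes ATP, 65 had a lower mean, with a median log2 fold change of -0.29. Uqcrc2, a core subunit of respiratory complex III, averaged 4028 normalised read counts in controls and 2468 in exposed females (n = 4 each), a log2 fold change of -0.70 ± 0.13. The 7 mitochondrially encoded subunits of that chain went the other way, all with a higher mean (median 0.25, adjusted p = 0.3 for the list). Fatty acid oxidation genes and PPARA targets were lower in 33 of 35 members (median -0.38). They included the fatty acid hydroxylase Cyp4a31 (2009 ± 232 against 1122 ± 41.2, -0.83 ± 0.11) and the acyl-CoA dehydrogenases Acadm (-0.54 ± 0.14) and Acadl (-0.58 ± 0.16). Mdh1 of the malate shuttle (-0.78), Sucla2 of the citric acid cycle (-0.67) and Vdac1, the channel of the outer mitochondrial membrane (-0.63), were also among the 10 genes of lowest p. Adjusted over the list alone, 29 of the 73 oxidative phosphorylation genes and 9 of the 35 fatty acid oxidation genes were lower and 0 were higher. No gene passed over all genes tested: limma called 0 of 14059 genes, with 2039 at an unadjusted p under 0.05 against 703 expected by chance, and the smallest adjusted p was 0.223. With limma voom 0 genes passed and 3097 had an unadjusted p under 0.05. The authors' deposited adjusted p values, given for 6790 of 14259 genes, counted 72 genes (20 higher and 52 lower in exposed livers). The list test (camera) gave adjusted p = 5.66e-17 for oxidative phosphorylation and 2.48e-08 for fatty acid oxidation at its preset correlation. Neither held when the correlation was taken from the data, with adjusted p = 0.642 with an estimated correlation for each.

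Several other groups of liver genes were lower in exposed newborns. Cytosolic ribosomal protein genes were lower in 65 of 72 members (median -0.19, adjusted p = 7.49e-07) and cholesterol synthesis genes in 24 of 25 (median -0.31, adjusted p = 0.000116), each with adjusted p = 0.79 with an estimated correlation and 0 members past the threshold adjusted over the list alone. All 15 measured megakaryocyte and platelet genes were lower (median -0.35, adjusted p = 0.00129, and adjusted p = 0.79 with an estimated correlation). Genes of periportal hepatocytes had a median of -0.29 (adjusted p = 0.00475, and adjusted p = 0.75 with an estimated correlation). Adjusted over the list alone, 4 of them were lower, among them the urea cycle enzymes Arg1 (9096 ± 3960 against 3918 ± 447, -1.12 ± 0.27) and Cps1 (-1.14 ± 0.29), against 0 over all genes tested. Retinoid genes went both ways, with 6 lower and 1 higher adjusted over the list alone against 0 over all genes, while the list test gave adjusted p = 0.112. Adh1 (-0.66), Adh7 (-0.93) and Aldh1a1 (-0.75), which oxidise retinol and retinal, were lower. The retinoic acid hydroxylase Cyp26b1 (1.14) was higher. Without Control replicate 1 the periportal list no longer passed (median -0.14, adjusted p = 0.0633).

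Groups with higher levels in exposed newborns belonged to blood formation, immune signalling and vessels. Erythroid genes were higher in 31 of 32 members (median 0.34, adjusted p = 7.32e-05) and interferon-stimulated genes in 30 of 34 (median 0.36, adjusted p = 1.04e-05), each with adjusted p = 0.79 with an estimated correlation. Sinusoidal endothelium genes had a median of 0.14 (adjusted p = 0.00173, and adjusted p = 0.642 with an estimated correlation), and 3 of them were higher adjusted over the list alone: the hyaluronan scavenger receptor Stab2 (3268 against 5132, 0.66 ± 0.11) and the VEGF receptors Flt1 (0.43) and Flt4 (0.46). Nlrc5, an activator of MHC class I genes, averaged 128 in controls and 367 in exposed livers (1.57 ± 0.29, adjusted p = 0.244). The fetal genes Afp (0.02 ± 0.28), Igf2 (0.02 ± 0.23) and H19 (-0.12 ± 0.20) differed by less than their standard error. The metallothionein genes, whose products bind cadmium and zinc, did not pass, with log2 fold changes of -0.13 ± 0.22 for Mt1 and -0.30 ± 0.20 for Mt2. In all, 14 of 42 lists passed at the preset correlation, 4 higher and 10 lower, and 0 with an estimated correlation. The erythroid list did not pass without Control replicate 2 (median 0.18, adjusted p = 0.118), and the cholesterol (-0.08, adjusted p = 0.546) and megakaryocyte (-0.16, adjusted p = 0.569) lists did not with the erythroid mean as a covariate. Leaving out Exposed replicate 3 gave 5 genes and leaving out Exposed replicate 4 gave 1.

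At PND21 the comparison asked which differences were present at weaning age. Exposed females had higher levels of cholesterol synthesis genes and lower levels of protein-folding and male-biased genes. Pmvk, which phosphorylates mevalonate on the way to cholesterol, rose from 517 ± 72.2 to 1622 ± 172 normalised read counts (n = 3 each, log2 fold change 1.65 ± 0.18, adjusted p = 0.0293), and Pctp, a carrier of phosphatidylcholine, rose from 48.4 ± 12.6 to 258 ± 45.3 (2.41 ± 0.29, adjusted p = 0.0473). The 3 other genes that passed were Gm11273 (10.49 ± 5.40 to 366 ± 65.2, 5.12 ± 0.44, adjusted p = 0.0143) and 2310007B03Rik (1.39 ± 0.065 to 61.5 ± 12.9, 4.69 ± 0.50, adjusted p = 0.0293), which rose, and the processed pseudogene Gm8730 (607 ± 305 to 12.3 ± 11.3, -5.75 ± 0.60, adjusted p = 0.0293), which fell. Their positions in mm10 were chromosome 3, 89454541 to 89469013 for Pmvk, chromosome 11, 89982665 to 90002894 for Pctp, chromosome 13, 21501029 to 21501418 for Gm11273, chromosome 1, 93151349 to 93160948 for 2310007B03Rik, and chromosome 8, 102864845 to 102865798 for Gm8730. In each case all 3 exposed libraries lay on the same side of the control mean. Limma called these 5 of 13886 genes, with 1329 at an unadjusted p under 0.05 against 694 expected by chance. With limma voom 32 genes passed (9 higher and 23 lower), and the authors' deposited table counted 446 (237 higher and 209 lower). The number called was 0 without Control replicate 3 or Exposed replicate 1, 1 without Control replicate 2, 2 without Control replicate 1, 3 without Exposed replicate 2 and 14 without Exposed replicate 3.

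Cholesterol synthesis genes were higher in 22 of 25 members (median 0.48, adjusted p = 3.92e-10, and adjusted p = 0.484 with an estimated correlation). Over all genes tested 1 of them passed. In all 7 were higher adjusted over the list alone, with Msmo1 (0.88 ± 0.18) and Fdft1 (0.97 ± 0.22) next to Pmvk. Stellate cell and extracellular matrix genes were higher in 37 of 40 (median 0.61, adjusted p = 1.37e-11, and adjusted p = 0.629 with an estimated correlation). Of these 5 were higher adjusted over the list alone against 0 over all genes, including elastin Eln (798 ± 250 against 3032 ± 1520, 1.84 ± 0.37) and the collagen gene Col1a1 (1.52 ± 0.35). Cell cycle genes were higher in 41 of 45 (median 0.74, adjusted p = 1.58e-06, and adjusted p = 0.734 with an estimated correlation) and B cell genes in 10 of 10 (median 0.83, adjusted p = 8.81e-06, and adjusted p = 0.523 with an estimated correlation). Markers of other tissues were higher in the same pieces. Cholangiocyte genes had a median of 0.76 (adjusted p = 0.0189, and adjusted p = 0.734 with an estimated correlation) and mesothelium genes of 0.78 (adjusted p = 0.0428, and adjusted p = 0.693 with an estimated correlation). Both measured genes of exocrine pancreas were higher, with a median of 1.37. The cholangiocyte list did not pass without Control replicate 3 (adjusted p = 0.0525) or Exposed replicate 3 (0.631), nor the mesothelium list without Control replicate 1 (0.0801), Control replicate 3 (0.0825), Exposed replicate 1 (0.282) or Exposed replicate 3 (0.0677). With the erythroid mean as a covariate the cholangiocyte median was 0.27 (adjusted p = 0.632), and that list did not pass with scaling by total reads either. The mesothelium list did not pass with the replicate block or with scaling by a trimmed mean of M values or total reads. Whether the matrix, cell cycle and B cell differences came with the tissue content of the pieces was not tested.

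Heat shock genes at PND21 were lower in 12 of 13 members (median -0.57, adjusted p = 8.67e-07, and adjusted p = 0.523 with an estimated correlation). Adjusted over the list alone 6 were lower, against 0 over all genes, among them the inducible HSP70 genes Hspa1b (432 ± 78.8 against 143 ± 16.6, -1.58 ± 0.22) and Hspa1a (-1.78 ± 0.42) and their co-chaperone Dnajb1 (-1.03 ± 0.17). Genes of the unfolded protein response had a median of -0.40 (adjusted p = 0.00148, and adjusted p = 0.523 with an estimated correlation). Of its members 7 were lower and 1 was higher adjusted over the list alone, including the endoplasmic reticulum chaperones Sdf2l1 (1486 ± 217 against 541 ± 104, -1.46 ± 0.20) and Hspa5 (-1.01 ± 0.22). Genes that are higher in male than female livers were lower in 22 of 23 (median -0.84, adjusted p = 1.52e-07, and adjusted p = 0.543 with an estimated correlation). Adjusted over the list alone 6 were lower and 1 was higher, with the complement genes C6 (1020 ± 220 against 394 ± 44.9, -1.35 ± 0.21) and C8b (-0.84 ± 0.25) lower and the repressor Bcl6 (0.64 ± 0.19) higher. Mt1 (0.53 ± 0.53) and Mt2 (0.36 ± 0.71) did not pass. In all, 14 of 41 lists passed at the preset correlation, 9 higher and 5 lower, and 0 with an estimated correlation. Scaling by total reads moved the median of all genes by 0.24 at PND21 and left the direction of each list named here as it was.

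In females at PND42, the comparison asked which differences were present in adolescence, in other animals than those of the younger ages. Genes made mostly in female livers were far lower in exposed females. The cytochrome P450 gene Cyp3a16 fell from 4538 ± 2570 to 65.1 ± 59.5 normalised read counts (n = 4 each, log2 fold change -6.85 ± 0.91, adjusted p = 4.98e-05; chromosome 5, 145436309 to 145469723) and the steroid sulfotransferase Sult2a1 fell from 2032 ± 1420 to 99.4 ± 117 (-5.41 ± 0.92, adjusted p = 0.00027; chromosome 7, 13796246 to 13837409). The plasma protein gene A1bg fell from 58160 ± 21300 to 5430 ± 2960 (-3.63 ± 0.54). Of 35 female-biased genes 20 fell and 0 rose over all genes tested, the same counts as adjusted over the list alone, with a median of -1.69 (adjusted p = 5.18e-05, and adjusted p = 0.617 with an estimated correlation). The genes with the largest rises were long ones: Lncpint, a long non-coding RNA, rose from 211 ± 98.3 to 2465 ± 404 (3.69 ± 0.53; chromosome 6, 31082565 to 31220488) and Nkain2 from 92.4 ± 26.8 to 1054 ± 407 (3.48 ± 0.27, adjusted p = 5.73e-07; chromosome 10, 31689310 to 32890462). Limma called 5269 of 13091 genes, 2468 higher and 2801 lower. Exposed females also differed from controls in 3 measures of their RNA, which are given next and accompany each group below.

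Mitochondrially encoded transcripts made up 27.6% ± 6.27 of the reads in exposed and 8.53% ± 3.13 in control females at PND42. Genes with over 300 kb of intron averaged 8.93 ± 0.16 on the log2 scale in exposed and 7.46 ± 0.20 in control females, and the nuclear RNAs Malat1 and Neat1 averaged 15.64 ± 0.18 and 13.81 ± 0.60. For each measure the 4 exposed libraries lay above the 4 controls (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows, and 0.114 adjusted over 12 tests). In the other 3 comparisons exact p ran from 0.2 to 0.6. Across genes, which are not independent replicates, fold change at PND42 rose with intron length in females, with a median of -0.21 for genes without introns, 0.66 for those with 100 to 300 kb and 1.41 for those over 300 kb. Of 338 genes over 300 kb, 253 rose and 1 fell. The same class had medians of 0.31 in PND1 females, 0.20 in PND21 females and 0.29 in PND42 males. Fold change also rose with the exon length of genes in PND42 females (Spearman 0.28, against 0.34 for intron length). The 2 values were 0.23 and 0.21 in PND42 males, 0.19 and 0.2 in PND1 females, and 0.06 and 0.06 in PND21 females. The measures thus do not single out intron length. All 7 measured mitochondrially encoded genes rose, including mt-Nd6 (6422 ± 2610 to 35110 ± 11600, 2.47 ± 0.29) and mt-Cytb (1.67 ± 0.35), with a list median of 1.68 (adjusted p = 0.00129, and adjusted p = 0.617 with an estimated correlation).

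**Figure D1:**
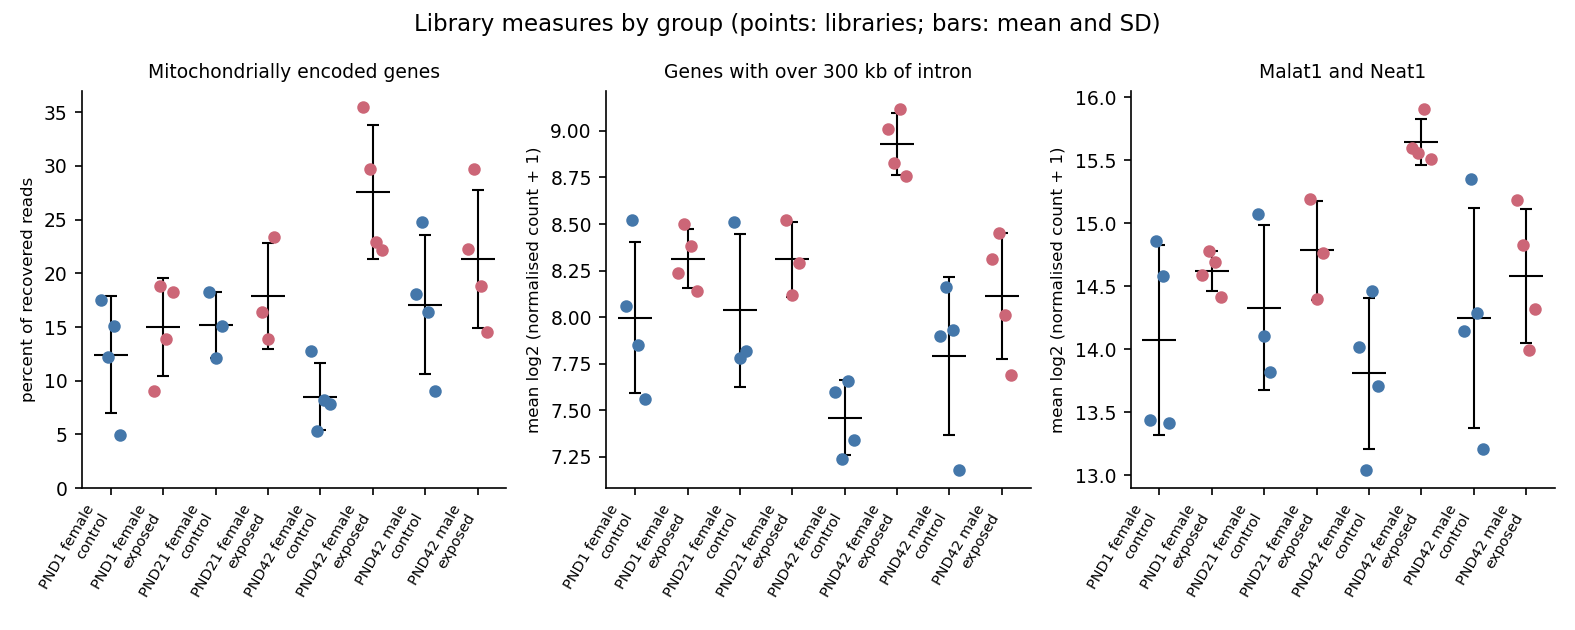
Share of reads from mitochondrially encoded genes (percent), mean log2 level of genes with over 300 kb of intron, and mean log2 level of Malat1 and Neat1, with 1 point per library and the mean and SD of each of the 8 groups. In PND42 females the 4 exposed libraries lie above the 4 controls in each panel (27.6% against 8.53% for the mitochondrial share).

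**Figure D2:**
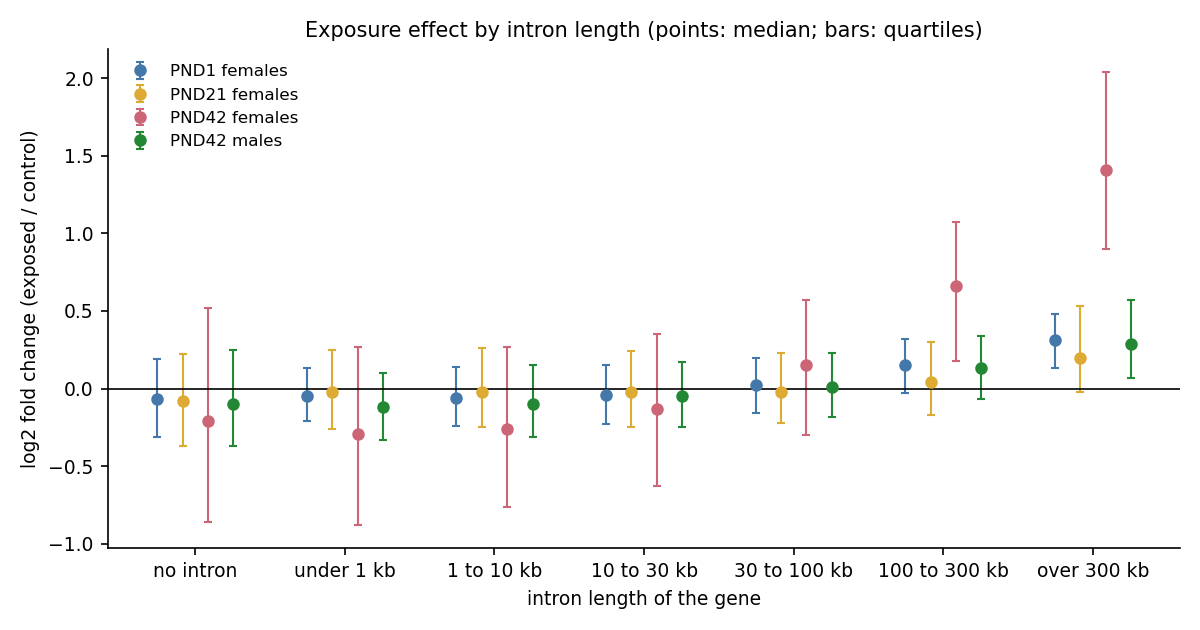
Median log2 fold change of exposed over control (points) with quartiles (bars) for genes grouped by total intron length, in each of the 4 exposure comparisons. In PND42 females the median runs from -0.21 in genes without introns to 1.41 in genes with over 300 kb of intron, and in PND42 males it is 0.29 in the longest class.

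Genes of energy metabolism in the nucleus went the other way from the mitochondrial genome in these PND42 females. Of 73 nuclear-encoded oxidative phosphorylation genes 36 fell and 2 rose (38 and 2 adjusted over the list alone). The ATP synthase genes Atp5f1 (9251 ± 747 to 2341 ± 279, -1.99 ± 0.31) and Atp5g1 (-1.87 ± 0.25) were among those that fell, and the list median was -0.61 (adjusted p = 5.18e-05, and adjusted p = 0.8 with an estimated correlation). Fatty acid oxidation genes fell in 18 of 35 members and rose in 1 (median -0.99, adjusted p = 0.000118, and adjusted p = 0.617 with an estimated correlation), and both counts were the same adjusted over the list alone. Etfdh (-2.04 ± 0.29) and Acads (-2.16 ± 0.34) fell while the receptor gene Ppara itself rose from 2494 ± 499 to 8294 ± 2250 (1.71 ± 0.29). Cytosolic ribosomal protein genes fell in 47 of 72 and rose in 0 (49 and 0 adjusted over the list alone, median -0.95, adjusted p = 2.59e-10), for example Rpl15 (2787 ± 103 to 611 ± 76.0, -2.20 ± 0.25) and Rps6 (-2.24 ± 0.29). Cholesterol synthesis genes fell in 12 of 25 and rose in 0 (13 and 0 adjusted over the list alone, median -0.73, adjusted p = 0.000863), with Idi1 at -3.12 ± 0.48. Both lists had adjusted p = 0.617 with an estimated correlation.

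Detoxification and stress-defence genes were also lower in exposed PND42 females. NRF2 targets and antioxidant enzymes fell in 17 of 29 members and rose in 1 (19 and 1 adjusted over the list alone, median -0.82, adjusted p = 5.18e-05), with the peroxide-removing enzymes Prdx1 (28940 ± 4250 to 4804 ± 1190, -2.61 ± 0.38) and Gpx1 (-2.16 ± 0.43) and the haem oxygenase Hmox1 (-2.09 ± 0.28). Drug-metabolising cytochromes P450 fell in 12 of 29 and rose in 0 (the same adjusted over the list alone, median -1.15, adjusted p = 0.00255), including Cyp2c29 (-3.13 ± 0.55) and Cyp2c37 (-2.94 ± 0.41). Unfolded protein response genes fell in 12 of 21 and rose in 0 (the same adjusted over the list alone, median -0.95, adjusted p = 0.00232), with the disulfide isomerase Pdia6 at -2.34 ± 0.25. Heat shock genes fell in 7 of 14 and rose in 1 (10 and 1 adjusted over the list alone, median -1.34, adjusted p = 0.00354), with Hspd1 at -1.77 ± 0.35. Of 14 genes for metallothioneins and zinc and cadmium transport, 6 fell and 0 rose (the same adjusted over the list alone, median -0.41, adjusted p = 0.014, and adjusted p = 0.475 with an estimated correlation). The zinc importer Slc39a4 fell from 1046 ± 244 to 259 ± 67.5 (-2.01 ± 0.21), and Slc39a8, which also carries cadmium into cells, fell by 1.60 on the log2 scale, while Mt1 (0.14 ± 1.4) and Mt2 (-0.53 ± 1.52) did not pass. The other 4 lists each had adjusted p = 0.617 with an estimated correlation.

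The acute phase, macrophage and matrix lists passed as lower in the same animals. Some other non-parenchymal lists did not pass. Sinusoidal endothelium genes rose in 5 of 23 and fell in 5 (the same adjusted over the list alone, adjusted p = 0.72). Cholangiocyte genes rose in 3 of 9 and fell in 3 (the same adjusted over the list alone, adjusted p = 0.945). B cell genes rose in 3 of 12 and fell in 0 (2 and 0 adjusted over the list alone, median 0.90, adjusted p = 0.115). T and NK cell genes had a lower mean in 6 of 9 (median -0.39, adjusted p = 0.651). Neutrophil and myeloid genes did in 4 of 5 (median -0.57, adjusted p = 0.507). All 3 mesothelium genes had a lower mean (median -1.03), too few for the list test. The lists were not tested against each other. Acute phase genes fell in 12 of 28 members and rose in 0 (the same adjusted over the list alone, median -1.05, adjusted p = 0.000875), including the fibrinogen genes Fgg (88660 ± 12000 to 19990 ± 10100, -2.27 ± 0.33) and Fgb (-1.79 ± 0.26). Kupffer cell and macrophage genes fell in 9 of 23 and rose in 0 (the same adjusted over the list alone, median -0.59, adjusted p = 0.00123), with C1qc at -2.07 ± 0.33. Stellate cell and matrix genes fell in 15 of 37 and rose in 0 (the same adjusted over the list alone, median -0.38, adjusted p = 0.00286), with the proteoglycans Bgn (-1.91 ± 0.23) and Lum (-1.90 ± 0.26). The acute phase, macrophage and matrix lists each had adjusted p = 0.617 with an estimated correlation. Albumin, Alb, fell from 2727000 ± 406000 to 1318000 ± 366000 (-1.08 ± 0.30, adjusted p = 0.00793). In all, 17 of 41 lists passed at the preset correlation, 1 higher and 16 lower, and 0 with an estimated correlation. Once each library's trend with intron length was removed, 3847 of the 5269 genes were still called in the same direction, 161 of the 5269 had changed sign, and 4613 genes were called in all. The removal changed the sign of Rora, a circadian regulator, from 1.28 to -0.42, and ended the call of Nrxn3 (3.16 to 0.81) among the genes with the largest rises.

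**Figure D3:**
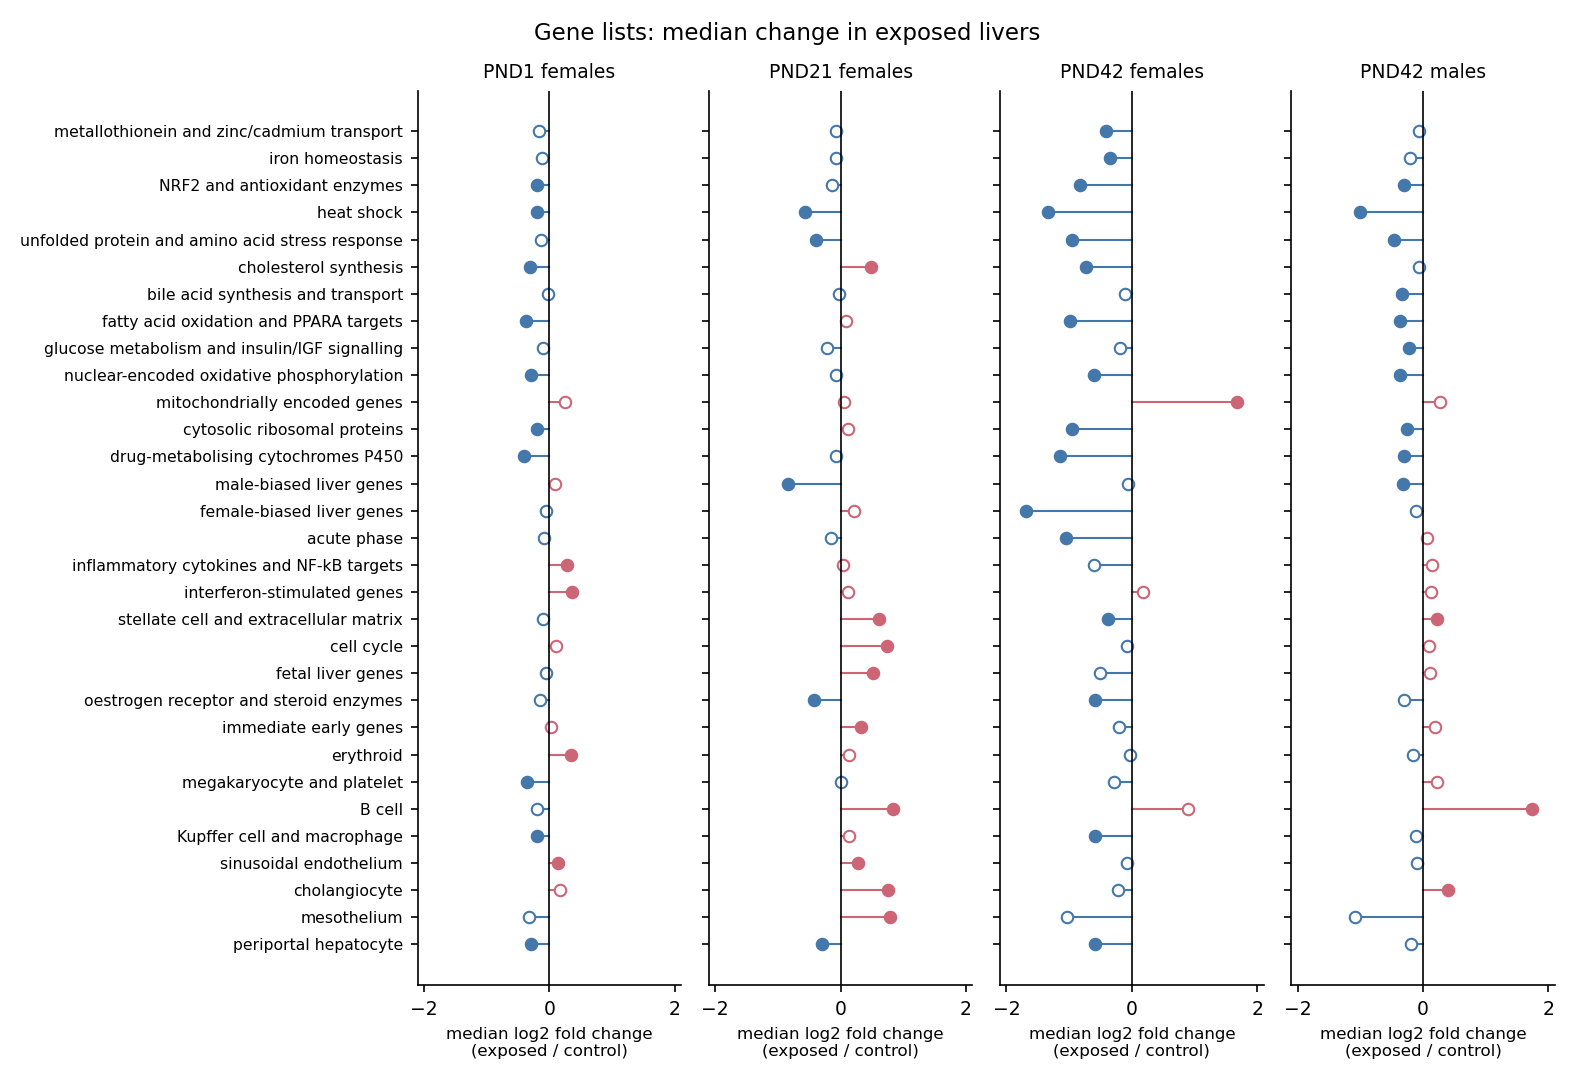
Median log2 fold change of exposed over control for the 31 gene lists that passed in at least 1 of the 4 exposure comparisons. Filled symbols have an adjusted p under 0.05 in the list test at its preset correlation and open symbols do not or were not tested. Oxidative phosphorylation lies at -0.29 in PND1 females, -0.61 in PND42 females and -0.37 in PND42 males.

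In males at PND42 the same exposure was examined at the same age. B cell genes were higher in the exposed males, in 11 of 12 members with a median log2 fold change of 1.74. Ighm, the heavy chain of immunoglobulin M, averaged 192 ± 83.1 normalised read counts in control and 500 ± 167 in exposed males (n = 4 each, 1.41 ± 0.33; chromosome 12, 113418558 to 113422730), the immunoglobulin D gene Ighd 22.2 ± 20.4 and 91.3 ± 4.12 (2.67 ± 0.66), and the B cell surface genes Cd22 and Ms4a1 had log2 fold changes of 1.27 ± 0.31 and 2.16 ± 0.56. Adjusted over the list alone 8 of the 12 were higher and 0 lower, against 0 over all genes tested. The mean log2 level of the list was 5.31 to 5.85 in the 4 exposed and 3.39 to 4.98 in the 4 control libraries. The list test gave adjusted p = 4.19e-10, and adjusted p = 0.156 with an estimated correlation. Markers of 2 other kinds of tissue were higher in the same males. Stellate cell and extracellular matrix genes were higher in 28 of 37 members (median 0.23, adjusted p = 0.00179, and adjusted p = 0.689 with an estimated correlation) and cholangiocyte genes in 9 of 9 (median 0.40, adjusted p = 0.0241, and adjusted p = 0.512 with an estimated correlation), each with 0 members past the threshold adjusted over the list alone. The matrix list did not pass without Control unnumbered a (0.26, adjusted p = 0.0905), nor the cholangiocyte list without Control unnumbered a (0.14, adjusted p = 0.121) or Exposed replicate 1 (0.16, adjusted p = 0.28). Heat shock genes were lower in 13 of 14 members (median -1, adjusted p = 3.22e-08, and adjusted p = 0.512 with an estimated correlation), and 5 were lower adjusted over the list alone, among them Hspa1b (1848 ± 1190 against 284 ± 86.3, -2.48 ± 0.61) and Hspa8 (-1.38 ± 0.47). Unfolded protein response genes had a median of -0.47 (adjusted p = 0.000411, and adjusted p = 0.512 with an estimated correlation), and 6 were lower adjusted over the list alone, for example Creld2 (-1.62 ± 0.50) and Herpud1 (-0.82 ± 0.23).

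Nuclear-encoded mitochondrial and antioxidant groups in the males had medians below 0, while the 7 mitochondrially encoded genes all had a higher mean (median 0.27, adjusted p = 0.284 for the list). Nuclear-encoded oxidative phosphorylation genes were lower in 72 of 73 members (median -0.37, adjusted p = 1.81e-11), fatty acid oxidation genes in 31 of 35 (-0.37, adjusted p = 5.7e-05) and NRF2 targets in 24 of 29 (-0.30, adjusted p = 0.00225), each with adjusted p = 0.689 with an estimated correlation and 0 members past the threshold adjusted over the list alone. Limma called 0 of 13091 genes, with 932 at an unadjusted p under 0.05 against 655 expected by chance and a smallest adjusted p of 0.622, and limma voom called 0 with 1448 at an unadjusted p under 0.05. The 10 genes of lowest p included the Wnt co-activator Bcl9 (0.94), the B cell linker Blnk (1.45) and the co-chaperone Dnaja4 (-1.37). Mt1 averaged 3043 ± 2880 in control and 21170 ± 36100 in exposed males (1.65 ± 1.4) and Mt2 differed by 1.17 ± 1.52, and in both the high mean came from Exposed replicate 1. In all, 13 of 41 lists passed at the preset correlation, 3 higher and 10 lower, and 0 with an estimated correlation. Without Control unnumbered a, 27 genes passed (14 higher and 13 lower), and 8 lists passed without Exposed replicate 1.

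**Figure D4:**
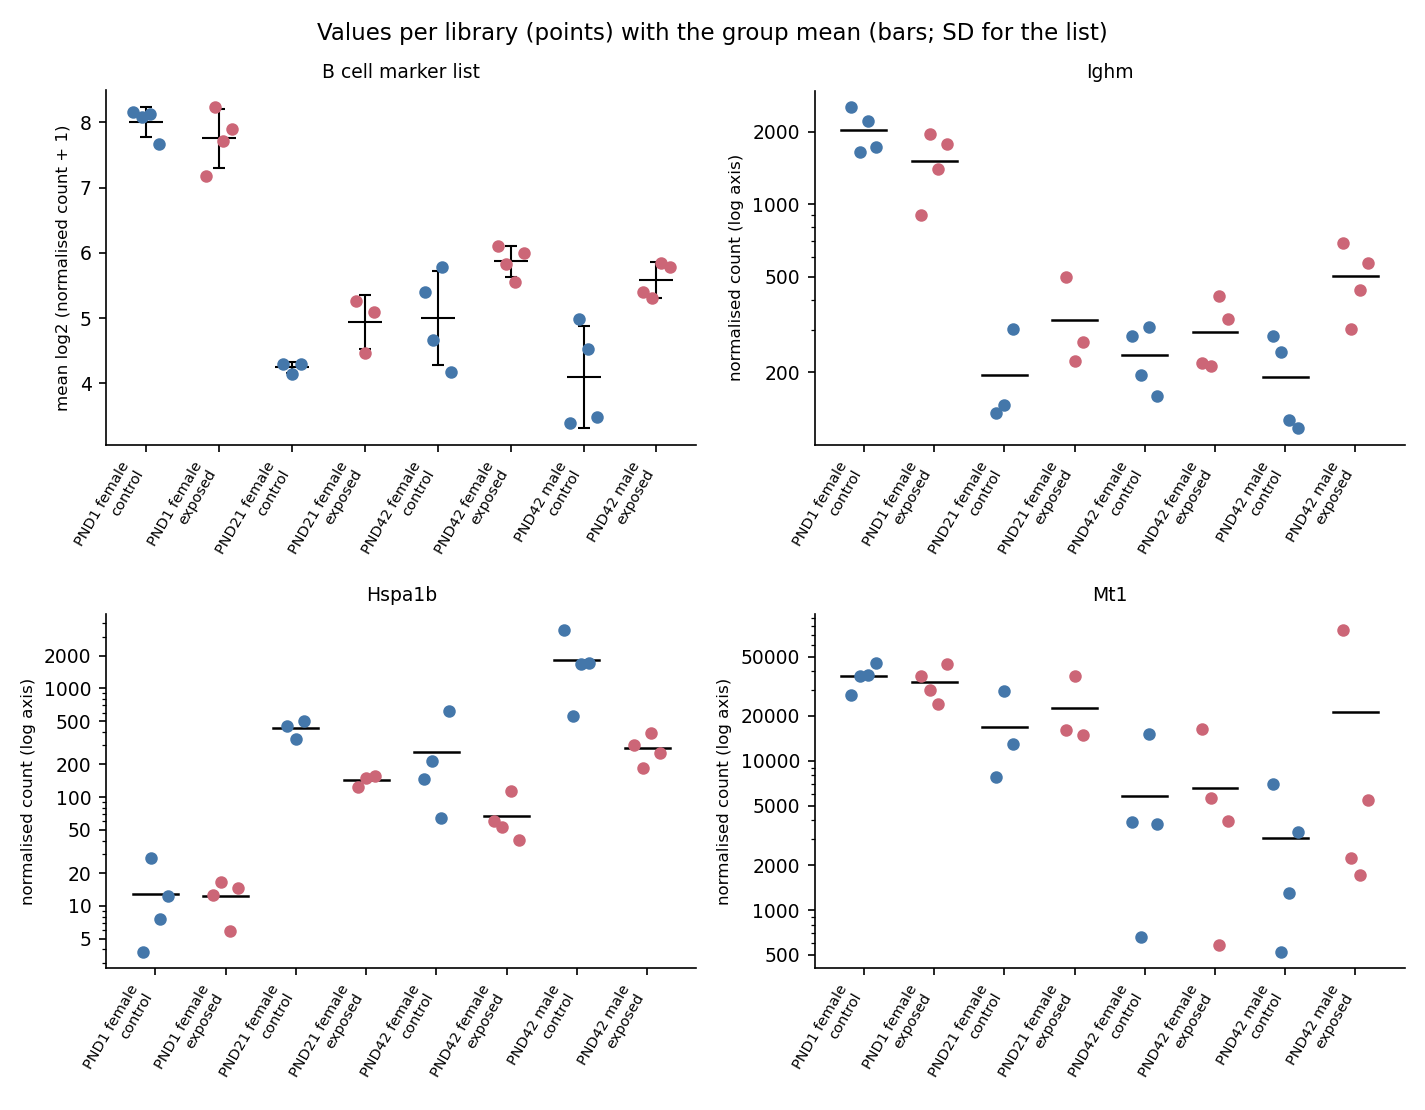
Mean log2 level of the B cell list with group mean and SD, and normalised read counts of Ighm, Hspa1b and Mt1 on log axes with group means as bars, with 1 point per library in each of the 8 groups. Exposed PND42 males lie at 5.31 to 5.85 for the B cell list and control males at 3.39 to 4.98, and 1 exposed male lies at 75200 for Mt1.

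The sexes were then set against each other at PND42 to ask whether exposure acted differently in females and males. Among the 8 genes of lowest interaction p, 3 with over 300 kb of intron differed between exposed and control females with little difference in males: Nkain2 differed by 3.48 ± 0.27 in females and -0.08 ± 0.27 in males, Naaladl2 by 3.02 ± 0.19 and 0.26 ± 0.19, and the tumour suppressor Fhit by 2.75 ± 0.21 and 0.13 ± 0.21. The basement membrane gene Nid1 differed by -2.09 ± 0.21 in females and 0.37 ± 0.21 in males, and Itm2c by -2.61 ± 0.22 and -0.11 ± 0.22. The class of genes with over 300 kb of intron had a median of 1.41 in females and 0.29 in males, without a test of the class between the sexes. The interaction passed for 1036 of 13091 genes, with the female effect the higher in 503 and the lower in 533, and in 228 and 551 of 779 with scaling by total reads. Of 35 female-biased genes 9 had a lower exposure effect in females and 0 a higher one (12 and 0 adjusted over the list alone, median difference -1.05, adjusted p = 5.64e-05). In controls this list had a median log2 fold change of female over male of 6.21. Most of its genes were thus low in males, where a fall would be harder to see, which limits this comparison. Acute phase genes had 8 lower of 28 (10 adjusted over the list alone, median -1.18, adjusted p = 4.98e-05), matrix genes 7 of 37 (8 adjusted over the list alone, median -0.79, adjusted p = 1.2e-06) and ribosomal protein genes 9 of 72 (17 adjusted over the list alone, median -0.70, adjusted p = 5.39e-08), each with 0 higher and with adjusted p = 0.782 with an estimated correlation, as for the female-biased list. Metallothionein and zinc transport genes had 4 lower of 14 (5 adjusted over the list alone, median -0.65, adjusted p = 0.00555, and adjusted p = 0.201 with an estimated correlation). The B cell list, which passed in males and not in females, did not pass here (adjusted p = 0.256). Among mitochondrially encoded genes 1 of 7 had a higher effect in females (7 adjusted over the list alone, median 1.42, adjusted p = 0.00209, and adjusted p = 0.782 with an estimated correlation). The count was 634 once each library's trend with intron length was removed and 2146 with limma voom. Leaving out 1 library gave 562 (female Control replicate 3), 606, 528 and 496 (female Exposed replicates 1, 2 and 3), 573 (male Control replicate 1), 1929 (male Control unnumbered c), 492 (male Exposed replicate 3) and 642 (male Exposed replicate 4).

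The exposure effect in females was also compared across the 3 ages. No list was tested for this comparison. Among the 8 genes of lowest p, the ribosomal protein gene Rpl15 differed by -0.39 ± 0.13 at PND1, -0.08 ± 0.25 at PND21 and -2.20 ± 0.25 at PND42, Rplp0 by -0.39, 0.53 and -1.93, and the respiratory chain gene Ndufa4 by -0.28, 0.39 and -1.95. The protease inhibitor Cstb differed by -0.24 ± 0.13, 0.73 ± 0.34 and -2.58 ± 0.29, and the proteasome gene Psmd13 by -0.10, 0.69 and -2.17. The joint test of the 3 effects passed for 3243 of 12795 genes shared by the tables. In 1662 of them the effect at PND21 was higher than at PND1, and in 1581 lower. The joint test does not say which ages differed, so these need not be changes between PND1 and PND21. PND1 and PND21 libraries shared a lane and a scaling, while PND42 libraries were on another lane and scaled apart, so that a difference of the PND42 effect from the younger ages went with lane as well as age. Scaling by total reads moved the median difference of all genes by 0.18 and the split to 2286 and 677.

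Exposure effects correlated positively across genes between every pair of the 4 comparisons, which asked whether the same genes moved at different ages. The highest correlation was between PND1 and PND42 females (Pearson 0.54, Spearman 0.61, jackknife SE over libraries 0.16, 12629 genes), and that between PND42 females and males was 0.44 (Spearman 0.51, SE 0.21, 13091 genes). PND1 females and PND42 males gave 0.34 (SE 0.17) and PND21 females and PND42 males 0.27 (SE 0.11). The correlations of PND21 females with PND1 (0.15, SE 0.19) and PND42 females (0.13, SE 0.30) were smaller than their errors. Genes are not independent replicates, and no p is given for these 6 correlations. Of the other splits of the PND42 males, that with the most genes called put 1 control with 3 exposed libraries. It correlated at 0.55 with the exposure effect in females, with its sides ordered to give a positive sign. That split was picked by its count and kept most libraries on their true side. It therefore cannot show whether a correlation of this size needs the true grouping by exposure. Whether these correlations came from exposure was not tested. At an unadjusted p under 0.01, 84 genes were higher in both PND1 and PND42 females against 29.0 expected, 225 were lower in both against 62.5 expected, and 0 moved in opposite directions. For PND21 and PND42 females 8 were higher in both against 22.5 expected, 57 lower in both against 30.1 expected, and 18 opposite. For PND42 females and males 33 were higher in both against 15.8 expected, 29 lower in both against 12.8 expected, and 3 opposite. PND1 and PND21 females shared 1 higher (2.2 expected) and 16 lower genes (3.4 expected) with 2 opposite, PND1 females and PND42 males 0 (1.3) and 8 (1.7) with 0 opposite, and PND21 females and PND42 males 5 (1) and 8 (0.8) with 0 opposite. Uqcrc2 (-0.70 at PND1) and the ATP synthase gene Atp5f1 (-0.55 at PND1 and -1.99 at PND42) belong to the oxidative phosphorylation list, which had a median below 0 at both ages.

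Control females and males at PND42 gave the reference for the sex-biased genes and a check of the labels. Of 35 female-biased genes 30 were higher in control females (34 adjusted over the list alone, median log2 fold change of female over male 6.21), and of 27 male-biased genes 19 were higher in control males (24 adjusted over the list alone, median -2.90). A1bg averaged 36.8 ± 16.2 normalised read counts in males and 58160 ± 21300 in females (n = 4 each, 10.60 ± 0.54), Cyp2b13 8.17 ± 2.74 and 5499 ± 2000 (9.19 ± 0.54), and Cyp3a44 27.0 ± 21.7 and 13160 ± 3650 (9.22 ± 0.66). The major urinary protein gene Mup20 averaged 114200 ± 44300 in males and 712 ± 248 in females (-7.30 ± 0.49), and the fatty acid hydroxylase Cyp4a12a 28540 ± 3520 and 122 ± 99.7 (-8.32 ± 0.67). Both lists passed with an estimated correlation (adjusted p = 0.00106 with an estimated correlation for each). Xist, transcribed from the inactive X chromosome, averaged 43.5 ± 9.46 in control males and 48270 ± 10500 in control females, and Ddx3y of the Y chromosome 3674 ± 469 and 0.410 ± 0.48. In all, 907 of 13091 genes passed, 307 higher and 600 lower in females. Kupffer cell genes were higher in females in all 23 members, of which 6 passed (15 adjusted over the list alone, median 0.79, adjusted p = 1.46e-08), and NRF2 targets fell below the male level in 11 of 29 (13 adjusted over the list alone, median -0.48, adjusted p = 2.38e-06), each with adjusted p = 0.421 with an estimated correlation. The share of mitochondrial reads also differed, at 8.53% in control females and 17.1% in control males. All 7 mitochondrially encoded genes had a lower mean in females, of which 5 passed (7 adjusted over the list alone, median -1.35, adjusted p = 6.39e-05, and adjusted p = 0.606 with an estimated correlation).

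The count of sex-biased genes depended on the scale and on single libraries, while both sex-biased lists kept their direction under each scaling and without each library. Scaling by total reads moved the median of all genes by 0.37 and gave 2110 genes (1875 higher in females and 235 lower). It was 2208 with limma voom and 392 when only the 2 control groups were fitted. Leaving out 1 library gave 386 (female Control replicate 3), 417 (female Control unnumbered), 496 (male Control replicate 1), 1979 (male Control unnumbered a) and 371 (male Control unnumbered b).

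Control females at PND1 and PND21 showed the maturation of the liver between birth and weaning. Blood-forming and fetal genes fell: 30 of 32 erythroid genes fell and 0 rose (the same adjusted over the list alone, median -4.51), all 15 megakaryocyte and platelet genes fell (15 adjusted over the list alone, median -4.38), and 17 of 19 neutrophil and myeloid genes fell while 1 rose (the same adjusted over the list alone, median -6.23), with the calprotectin gene S100a9 going from 13430 ± 1330 (n = 4) to 126 ± 28.2 (n = 3, -6.74 ± 0.21). Fetal liver genes fell in 26 of 29 members (27 adjusted over the list alone, median -3.04), led by Afp (253200 ± 81400 to 682 ± 122, -8.49 ± 0.44), while 23 of 28 imprinted genes fell and 3 rose (the same adjusted over the list alone, median -2.71), with H19 at -7.59 ± 0.49 and Igf2 at -8.22 ± 0.42. Cell cycle genes fell in 44 of 45 (44 adjusted over the list alone, median -3.54), with Mcm2 at -3.49 ± 0.28. Genes of the mature liver rose, including 17 of 29 drug-metabolising cytochromes P450 (19 adjusted over the list alone, median 1.48), with Cyp1a2 going from 384 ± 243 to 14380 ± 1510 (5.40 ± 0.42), and 14 of 18 periportal genes (the same adjusted over the list alone, median 1.93), with Arg1 at 2.59 ± 0.37. Male-biased genes rose in 18 of 23 (the same adjusted over the list alone, median 2.84), and the major urinary protein gene Mup3 rose from 44.0 ± 13.7 to 88020 ± 43500 (10.85 ± 0.32). Igf1, which growth hormone induces, rose by 4.17 ± 0.26 and the growth hormone receptor gene Ghr by 2.58 ± 0.21. Each of these lists passed at the preset correlation, with adjusted p from 4.28e-16 for the erythroid to 0.000118 for the periportal list, and none passed with an estimated correlation (the smallest was adjusted p = 0.0811 with an estimated correlation).

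In all, 7985 of 14259 genes passed between the ages, 3944 higher and 4041 lower at PND21. Scaling by total reads moved the median of all genes by -0.51 and gave 1785 higher and 6865 lower genes, and the acute phase list changed from a median of 0.46 to -0.06, whereas Orm1, a plasma carrier protein gene of that list, was higher at PND21 by 7.57 ± 0.34.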

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

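The measures of mitochondrial, long-intron and nuclear RNA and the tests of blood in the liver pieces and of intron-length and GC trends in this part were chosen after the results were seen.

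In exposed PND42 males, Exposed replicate 1 stood apart in Mt1, at 75200 normalised read counts against 1710 to 5500 in the other 3, and in Mt2, at 34200 against 864 to 2090. The same library had the lowest mean of periportal hepatocyte genes, 12.58 on the log2 scale against 13.42 for the next. Among control males, Control unnumbered a had a pericentral hepatocyte mean of 10.47 against 11.20 for the next. At PND42, female Control replicate 2 had an erythroid mean of 8.76 against 9.01. At PND1, Exposed replicate 3 had a megakaryocyte and platelet mean of 9.64 against 8.85, and Control replicate 4 a B cell mean of 7.67 against 8.08. Chance singles out about 1 in 20 by this rule, so 5.8 of the 116 combinations of group and measure tested would be expected, and 7 were found. The combinations share libraries and are not independent of each other.

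The test of a different exposure effect in the sexes at PND42 passed for 1036 genes. The differences of female minus male effect were 2.76 for Naaladl2, 3.56 for Nkain2, 2.63 for Fhit, 1.63 for Dip2c, 2.35 for Egfem1 and 1.55 for Lyrm4, and -2.46 for Nid1 and -2.50 for Itm2c. Of 100 drawn splits of the libraries, 4 gave at least as many genes, the real one included, and the highest other gave 6616, several times the real count, which points to a structure of the samples. Of the 99 other splits, the 3 that kept the PND42 female groups all called more genes than the real one (at least 2345), and the 96 that parted them called at most 4. The count thus follows the female difference. Each split either kept that difference or took it away, so that the splits cannot test the sex interaction. Chance stays open for it, and the count does not by itself show that the sexes responded differently. The test of a different exposure effect by age in females passed for 3243 genes. The effect at PND42 minus that at PND1 was -2.35 for Cstb, -2.07 for Psmd13, -1.67 for Ndufa4, -1.80 for Rpl15, -1.42 for Msrb1, -1.96 for Rpl41, -1.54 for Rplp0 and -1.92 for Nop10. Of 100 drawn splits 3 gave at least as many genes, the real one included, and the highest other gave 5333. The 3 other splits that kept the PND42 female groups called at least 3190, and the 96 that parted them called at most 1. This count follows the PND42 difference in the same way, and for the same reason the splits cannot test the age interaction. Chance stays open for it, and the count does not by itself show that the effect depended on age.

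The difference between exposed and control females at PND42, with genes of long introns higher in the exposed, was weighed against 3 technical explanations. The real split called 5269 genes and was the only 1 of 35 to call as many, and the highest other split called 0. Chance is thus unlikely but not excluded, since 35 splits allow no share below 1 in 35. A shift of each library linked to intron length, as unspliced or nuclear RNA would give, was not the whole cause, since 73.0% of the genes stayed called in the same direction once that trend was removed, and GC content was not either, with 97.6%. Genomic DNA in the exposed libraries would raise every gene by about the same amount per exon length. In exposed females 29.8% of tested genes lay below the median rise per exon length of the 253 long-intron genes called higher. DNA was thus not the source of that whole median rise. These genes were picked because they rose, and a smaller share from DNA was not tested. A trend with exon length was not removed or weighed. That trend, nuclear or unprocessed RNA beyond the removed trend, genomic DNA as a part of the rise, the handling of the tissue and an effect of exposure in females stay open. With 27.6% against 8.53% mitochondrial reads, the exposed or the control libraries may differ in RNA handling as well as in exposure. The control females had the lowest mean share of all groups (next 12.4%, in PND1 controls), and the exposed females the highest (next 21.3%, in PND42 exposed males).

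The lower oxidative phosphorylation genes in PND1 exposed females, with a median of -0.29, were weighed next. The median was -0.25 with the intron-length trend removed, -0.32 with the erythroid mean as a covariate, and -0.26 at its closest to 0 on leaving out each control library, so that none of the intron-length shift, the blood-forming share or a single control library was the whole cause. At the level of genes 0 passed by limma, with 2039 at an unadjusted p under 0.05 and 0 by limma voom. With a real count of 0 all 35 of 35 splits call at least as many by construction (the highest other called 2), which says nothing on chance. A lower level of these transcripts after exposure may be a biological difference, as a hypothesis, and other technical sources were not tested.

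The higher B cell genes in exposed PND42 males, with a median of 1.74, were weighed last. More blood in the exposed pieces would raise erythroid genes, whose median was -0.16, and an equal rise of leukocytes of every kind would raise T and NK cell genes by about as much as B cell genes. The median of the 9 T and NK cell genes was 0.07 (SD 0.73 between genes, 5 higher and 4 lower), which argues against an equal rise. Genes of neutrophils and myeloid progenitors had a median of 0.80 with 4 of 5 higher, but the list mean was 10.13 in Exposed replicate 1 and 6.12 to 7.82 in the other 3 exposed males against 6.63 to 7.09 in controls, and without that library the median was -0.25. A single exposed library was not the source of the B cell difference, since the lowest B cell median on leaving each out was 1.69. The B cell list mean was 3.39, 3.48, 4.52 and 4.98 in control males and 5.31 to 5.85 in exposed males. In control females it was 4.17 to 5.78. Among controls the list was higher in females than in males, with a median of 0.71 to 1.29 on leaving out each library. A low level in the control males therefore stays open as well as a rise in the exposed males. Matrix genes (28 of 37 higher, median 0.23) and cholangiocyte genes (9 of 9, median 0.40) were higher with the B cell genes, as more portal tissue in the pieces would have it. Neither list passed without Control unnumbered a, although the matrix median was then 0.26, with 0.14 for cholangiocyte and 2.25 for B cell genes. A different amount of lymphoid or portal tissue with each piece stays open, as does a larger number of B cells in the exposed liver, which may be put forward only as a hypothesis.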

How the results depend on the processing

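The trimmed mean of M values, total-read scaling, pseudocounts and removal of intron-length or GC trends were tried after the data were seen, and the other alternatives were planned. The planned count-model fits and the PND42 against PND21 control comparison were not run, and the replicate block had no value in PND42 males, the sex interaction or the sex difference. The correlations of exposure effects, 7985 age-related genes (6465 to 8650), 3243 age-interaction genes (2500 to 3856) and 5269 genes in PND42 females (3950 to 6774) kept within 1.5 times their count or within their error under every alternative tried. Counts moved by more in the following, and the cause was not tested unless fewer libraries or genes show it. At PND21, where 5 genes passed, limma voom gave 32, a mean of 1 read per M reads 3, the replicate block 8 and the erythroid covariate 3. The sex interaction gave 2146 genes with limma voom and 634 without the intron-length trend, of the 1036. The sex difference gave 2208 with limma voom, 2110 with total reads and 392 with the 2 groups alone, of the 907. With an estimated correlation 0 lists passed in each of the 4 exposure comparisons, and with fry 0 passed at PND1, 0 at PND21, 19 in PND42 females and 1 in PND42 males, against 14, 14, 17 and 13 at the preset correlation.

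Leaving out each library in turn gave 0 to 5 genes at PND1, 0 to 14 at PND21, 4234 to 4894 in PND42 females and 0 to 27 in PND42 males, 492 to 1929 for the sex interaction, 371 to 1979 for the sex difference, 2636 to 3763 for the age interaction and 7041 to 7813 for the age difference. The lists that passed numbered 12 to 17, 13 to 19, 15 to 18 and 8 to 21 in the 4 exposure comparisons. Without male Exposed replicate 1 it was 8, and without Exposed replicate 2 it was 21. Fewer libraries lower the power of each of these fits.

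Directions reversed in 13 values of the genes that the naming rule gave in the exposure comparisons. Genes named only as reference levels that did not pass were left out of this count. Among those left out, Xist at PND21 went from -0.14 to 0.09 with scaling by total reads. Mt1 was 0.02 at PND1 without Exposed replicate 3 (-0.28 without Exposed replicate 4), and Mt2 at PND21 was -0.33 without Control replicate 1 and -0.11 without Exposed replicate 2, against 1.04 without Control replicate 2. In PND42 females Mt1 was -0.52 with the replicate block, -0.11 with the erythroid covariate, and -0.66, -0.56 and -0.05 without Control replicate 3, Exposed replicate 1 and Exposed replicate 2, against 1.04 without Exposed replicate 3. Mt2 there was 0.13 without Control replicate 4 and 0.39 without Exposed replicate 3, against -1.37 without Exposed replicate 1, and Rora was -0.42 without the intron-length trend. In PND42 males Mt2 was -0.19 with limma voom and -0.01 without Exposed replicate 1, against 1.83 without Control replicate 1. Of the other values of named genes 3213 kept their direction and side of the threshold in PND42 females, 98 lost it and 1 gained it, and 701, 777 and 408 kept both at PND1, PND21 and in PND42 males. At PND21 35 lost and 18 gained the call, and in PND42 males 5 gained it. Replicate numbers paired no samples, with correlations between same-numbered libraries from -0.08 to 0.23. At PND21 71% of 4-fold and 22% of 2-fold changes were recovered in simulated data, so that most 2-fold differences would have been missed there.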

Other observations

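The tests of scaling, of pseudocounts and of the intron-length and GC trends in this part were chosen after the results were seen.

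Single genes passed in further gene groups in PND42 females, most of which did not pass as lists. Over all 13091 genes tested 2468 rose and 2801 fell, so that counts near those shares do not set a group apart. Imprinted genes rose in 5 of 20 members and fell in 1, the same counts as adjusted over the list alone (adjusted p = 0.238 for the list), with the antisense RNAs Kcnq1ot1 (281 ± 79.5 to 1006 ± 114, 1.88 ± 0.38) and Airn (2.24 ± 0.50) among those that rose. Genes of glucose metabolism and insulin signalling rose in 4 of 32 and fell in 6, as they did adjusted over the list alone (adjusted p = 0.72), with Foxo1, a transcription factor of the fasted liver, at 1.12 ± 0.20 and the growth factor carrier Igfbp3 at -2.01 ± 0.29. Retinoid genes rose in 4 of 32 and fell in 11 (4 and 12 adjusted over the list alone, adjusted p = 0.16), among them the storage enzyme Lrat (-1.24 ± 0.25) and Rdh10 (-1.09 ± 0.14). The bile acid importer Slc10a1 fell from 20900 ± 3290 to 6254 ± 557 (-1.73 ± 0.31), and 4 of 20 genes of bile acid synthesis and transport fell and 0 rose (the same adjusted over the list alone, adjusted p = 0.651). Iron genes fell in 8 of 17 and rose in 1 (the same adjusted over the list alone, median -0.35, adjusted p = 0.0411, and adjusted p = 0.617 with an estimated correlation), with the ferritin gene Ftl1 at -2.19 ± 0.24 and Bmp6, which induces hepcidin, at 1.55 ± 0.29. That list did not pass without Control replicate 2 (adjusted p = 0.0579), Control replicate 3 (0.0612), Control unnumbered (0.0503), Exposed replicate 3 (0.0617) or Exposed replicate 4 (0.0554), nor once the intron-length trend was removed (0.0542). Hepatocyte zonation genes fell on the portal side in 8 of 18 members and rose in 0 (the same adjusted over the list alone, median -0.59, adjusted p = 0.00263, and adjusted p = 0.617 with an estimated correlation), and on the central side fell in 6 of 22 and rose in 1 (the same adjusted over the list alone, adjusted p = 0.387), with Cyp2e1 at -1.57 ± 0.43 and the stem cell receptor Lgr5 at 1.86 ± 0.45.

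At PND21 fetal liver genes were higher in 22 of 25 members (median 0.52, adjusted p = 0.000483, and adjusted p = 0.734 with an estimated correlation), and 3 were higher adjusted over the list alone against 0 over all genes, among them Lgals1 (1.28 ± 0.31) and Pkm (0.86 ± 0.22). Without Exposed replicate 3 that list had a median of 0.12 (adjusted p = 0.235), and with the erythroid mean as a covariate it had 0.11 (adjusted p = 0.632). The p53 targets Cdkn1a (1.23 ± 0.27), Gdf15 (1.79 ± 0.40) and Bbc3 (1.07 ± 0.26) were the 3 of 23 that were higher adjusted over the list alone, against 0 over all genes (adjusted p = 0.134 for the list). The bile acid repressor Nr0b2 averaged 504 ± 96.0 in controls and 2609 ± 1410 in exposed females (2.26 ± 0.34, adjusted p = 0.168).

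Skeletal muscle RNA was present in single libraries, with Mylpf at 6020 normalised read counts in PND1 Control replicate 2 against 72.6 to 121 in the other 7 PND1 libraries, and at 1910 in PND42 female Exposed replicate 4 against 16.5 to 113 in the other 3 exposed and 19.4 to 29 in the 4 control females of that age. No pair of libraries within a group was a duplicate, with Pearson correlations of log2 values from 0.916 to 0.976.

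Other splits of the samples were counted for the remaining comparisons. At PND21 the real split called 5 genes and 2 of 10 splits called as many, the highest other 5, and 10 splits are too few for a share under 0.05. In PND42 males the real split called 0 genes by limma, with 932 at an unadjusted p under 0.05 and 0 by limma voom. All 35 of 35 splits therefore call at least as many by construction, which says nothing on chance. The highest other called 2589, which points to a structure of the samples. That split exchanged Control unnumbered a with Exposed replicate 3. With its sides ordered to give a positive sign, its fold changes correlated at 0.55 across genes with the exposure effect in females. In that order 1632 of its genes were called in females in the same direction and 11 in the opposite one. The Malat1 and Neat1 mean was 14.32 to 15.35 on the log2 scale on the side with Control unnumbered a and 13.21 to 14.29 on the other, while the mitochondrial share (14.5% to 29.7% against 9% to 18.8%) and the mean of genes with over 300 kb of intron (7.69 to 8.45 against 7.18 to 8.01) overlapped between the sides. The sex difference called 907 genes against a highest other of 203, and the age difference 7985 against 4468. Each was the only 1 of 35 splits to call as many, so that chance is unlikely but not excluded for both.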
